A study of Mus musculus with 40 samples.

How the data were processed

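The 40 arrays are those of the labels' groups, with 7 naive arrays, 3 at 8 h, 16 h, 1, 2, 3, 5, 6, 7 and 8 days and 2 at 4, 9 and 10 days after spared nerve injury; behaviour was not used here. Per the labels, biotin-labelled cRNA was hybridized to Illumina bead arrays. Per the file headers, the table of 25697 probes holds a signal (intensity) and a detection p-value for each array. The authors' deposited second table holds log2 values, which lie within 0.038 of the log2 of the quantile-normalized signals. Column names were matched to the labels. The detection column of 10-day replicate 2 is named for 216 h (9 days) while its signal column and label say 240 h (10 days), and the array was kept as labelled, so its values at 10 days carry that doubt.

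The plan, fixed before the data were examined, was neqc background correction with the deposited detection p-values. On 37 of 40 arrays the deposited detection p-values do not fall as the same array's signal rises, so they cannot serve as that array's own detection. The plan was therefore changed after the files and an initial neqc fit had been seen. Signals were background-corrected with normexp (offset 50), quantile-normalized and brought to log2. The detection level is the lowest normalized log2 value with a detection p under 0.05, averaged over the 3 arrays whose column follows their signal (6.85; range 6.82 to 6.88). Probes above it on at least 3 arrays were kept (15462). The neqc fit stays as an alternative with 11084 genes tested; it gave 93 genes early, 1153 in the middle phase, 1154 late, 749 for late minus early and 804 at any time. Of 275 gene values past the threshold, 88 were over 1.5 times closer to 0 with neqc and 11 lost their call.

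Probes were assigned to genes by the platform's probe table (23978 with 1 gene symbol, 1719 with none), with Entrez numbers matched to RefSeq names of GRCm38.p6 for 23962 probes. No coordinates were used. Each gene is represented by its kept probe with the highest mean signal (10519 genes, 2819 of them with several probes). Where no array of a group lay above the detection level, the text gives a difference of at least N-fold, computed from the mean of the phase minus the mean of the reference with values below the level raised to it; it holds for this normalization, and neqc gives smaller values.

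Genes were tested with limma (version 3.58.1 in R 4.3.3), with 1 mean per group over all 40 arrays, moderated variances with a trend, a moderated F-test over the 12 times, each time against naive, the means of the early, middle and late times against naive, and late minus early. P-values were adjusted by Benjamini-Hochberg (BH) over genes within each comparison, with a threshold of 0.05. Counts adjusted over the list alone use BH over the list's measured members. Lists with at least 5 measured genes (30 of 32) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with BH over all lists and 4 comparisons together. The estimated correlation was 0.215 in the injury list and 0.326 in the extracellular matrix list. It was 0.384 in the neutrophil and mast cell list and 0.861 in the skeletal muscle list. In lists with such correlations the preset gives far smaller p-values. A camera adjusted p printed alone is from the preset. The lists, fixed in advance from general knowledge, cover nerve-injury and regeneration genes, immediate-early genes, sodium, potassium, calcium and transduction channels, peptidergic and nonpeptidergic nociceptor and large-fibre neuron markers, inhibitory receptors, macrophage, lymphocyte, and neutrophil and mast cell markers, and complement genes. They further cover cytokines and chemokines, interferon-stimulated and antigen presentation genes, satellite glia, myelin, repair Schwann cell, proliferation, cholesterol synthesis, extracellular matrix, endothelial, clock, glucocorticoid, unfolded protein response, oxidative phosphorylation, erythrocyte, skeletal muscle, adipocyte, and spinal and oligodendrocyte genes; some genes are in more than 1 list. Named genes are the 10 largest per direction and phase, members of the lists and genes named in advance. The 10 largest were taken among genes past the threshold whose group means all lay in that direction. For late minus early, every late group mean had to lie beyond every early group mean. This choice favours agreement of the single arrays, so that agreement is not separate support.

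With known differences added to simulated arrays of the same layout, the late comparison called 88% of genes with a log2 difference of 0.5 and 100% from 1 on, and 0.126% of unchanged genes. The 8-day comparison called 64% at 0.5, 94% at 1 and 100% from 2 on, and 0.0872% of unchanged genes. The simulated genes varied independently of each other. On the real arrays 38.1% of the within-group variance lay on the first axis, so these rates need not hold for them. The median standard deviation of a gene within groups was 0.185 log2. No arrays were duplicates of each other (highest correlation 0.995).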

Results

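RNA of dorsal root ganglia, which hold the cell bodies of sensory neurons, was measured on 40 Illumina bead arrays from adult male C57BL/6J mice. In spared nerve injury a pair of sciatic nerve branches, tibial and common peroneal, are tied and cut, and the sural branch is left intact. Naive mice gave 7 arrays. Groups of 3 arrays followed the injury at 8 h, 16 h, 1, 2, 3, 5, 6, 7 and 8 days, and groups of 2 arrays at 4, 9 and 10 days. The median signal per array lay between 130.2 and 244.5 intensity units, and 10519 genes had a probe above the detection level on at least 3 arrays. The number of arrays limits the precision of every value. The labels do not say whether an array holds RNA of 1 mouse or of a pool. The p-values therefore measure the spread between these samples, part of which can be technical. The injury marker Atf3 separated the labels, with a normalized log2 signal of at most 7.54 on the naive arrays and at least 8.45 on the injured arrays. Log2 differences are given with their standard error, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

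The time points against naive ganglia address when expression changes during the 10 days in which the series also followed behaviour, which was not used here. At 8 h, Chil3, a chitinase-like protein of myeloid cells, rose by 1.61 ± 0.30 (adjusted p = 0.0095, n = 3 against 7). Atf3, an injury-induced transcription factor, rose by 1.44 ± 0.16 (adjusted p = 8.49e-07) and Socs3, a feedback inhibitor of cytokine signalling, by 1.22 ± 0.15 (adjusted p = 9.44e-06). The only gene that fell at 8 h was Ccnd1, which encodes cyclin D1, with a difference of -0.54 ± 0.11 (adjusted p = 0.0329). Atf3 was past the threshold at all 12 times and reached 3.64 ± 0.16 at 16 h. Gpr151, an orphan receptor, was past it from 16 h (1.45 ± 0.15). The neuropeptide genes Npy (1.61 ± 0.25) and Gal (1.25 ± 0.14) and the regeneration-associated gene Sprr1a (1.05 ± 0.22) were past it from 1 day. So were the cholecystokinin receptor gene Cckbr (adjusted p = 6.94e-05) and the macrophage growth factor gene Csf1 (0.95 ± 0.16). The complement gene C1qb (0.77 ± 0.17), the muscle and fat carbonic anhydrase gene Car3 (1.45 ± 0.38) and the endopeptidase gene Ecel1 (1.36 ± 0.18) were past it from 2 days. C1qa was past it from 6 days (0.81 ± 0.17). Socs3 was past it at 7 times, from 8 h to 5 days, and Bdnf, which encodes a neurotrophin, at 5 times, from 16 h to 4 days. At 10 days the largest differences were in Npy (5.35 ± 0.28), Cckbr (3.97 ± 0.26) and Gpr151 (3.94 ± 0.18; n = 2 against 7). On the lower side they were in Calb2, a calcium-binding protein gene (-1.61 ± 0.16), Vstm2b, a membrane protein gene (-1.33 ± 0.18), and Whrn, a scaffold protein gene (-0.81 ± 0.14). At 8 h the call of Chil3 ended without 8-hour replicate 1 (adjusted p = 0.244) or 3 (adjusted p = 0.108). That of Ccnd1 ended without any of 7 single arrays (adjusted p between 0.0593 and 0.493), with the mean of its probes (adjusted p = 0.187) or with only the arrays of the groups compared (adjusted p = 0.129). With neqc background correction, Atf3 at 8 h was 0.75 (adjusted p = 0.0598), Chil3 0.93 and Calb2 at 10 days -0.97.

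**Figure D1:**
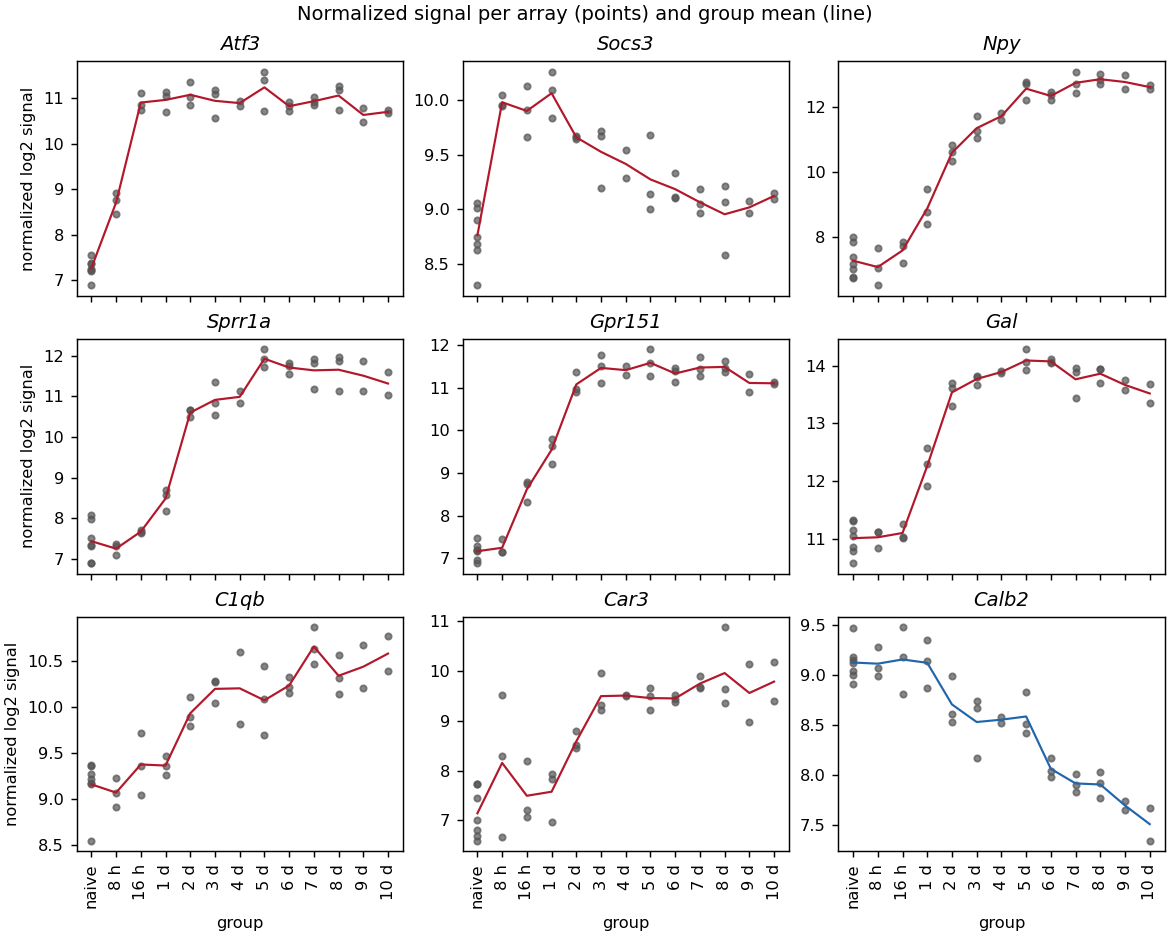
Normalized log2 signal of 9 genes on each array (points) with the group means (lines), from naive to 10 days after the injury. Atf3 and Socs3 lay above naive at 8 h, Npy, Sprr1a and Gal rose over the following days, and Calb2 fell.

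Over all times, 791 genes passed the moderated F-test. This is not a total of the genes that changed, since 1150 passed in the middle phase alone. With 1 array left out the F-test count ranged from 688 to 1114, and other settings given below moved it further. The number of genes that differed from naive was 11 at 8 h (10 higher, 1 lower), 75 at 16 h (57 higher, 18 lower), 174 at 1 day (134 higher, 40 lower), 406 at 2 days (253 higher, 153 lower) and 612 at 3 days (386 higher, 226 lower). It was 258 at 4 days (204 higher, 54 lower), 729 at 5 days (413 higher, 316 lower), 547 at 6 days (294 higher, 253 lower) and 636 at 7 days (415 higher, 221 lower). It was 440 at 8 days (274 higher, 166 lower), 213 at 9 days (172 higher, 41 lower) and 295 at 10 days (230 higher, 65 lower). With robust variances and array weights the split was 256 higher and 233 lower at 1 day, 503 higher and 492 lower at 2 days, 616 higher and 761 lower at 6 days and 132 higher and 25 lower at 9 days. Groups of 2 arrays (4, 9 and 10 days) have less power, so the counts do not rank the times. Single arrays moved many of these counts. At 8 h the count was 3 without 8-hour replicate 1 and 20 without 10-day replicate 1 or 2. At 16 h it was 37 without replicate 1 and 43 without replicate 2, at 1 day 83 without replicate 2 and 87 without replicate 3, and at 2 days 265, 268 and 193 without replicates 1, 2 and 3. At 3 days it was 1040, 366 and 323 without replicates 1, 2 and 3, at 4 days 137 and 85 without replicates 1 and 2, and at 5 days 407 and 427 without replicates 2 and 3. At 6 days it was 303 and 299 without replicates 2 and 3, at 7 days 305 without replicate 2, and at 8 days 264 without replicate 2. At 9 days it was 70 and 129 without replicates 1 and 2, and at 10 days 87 without replicate 1.

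**Figure D2:**
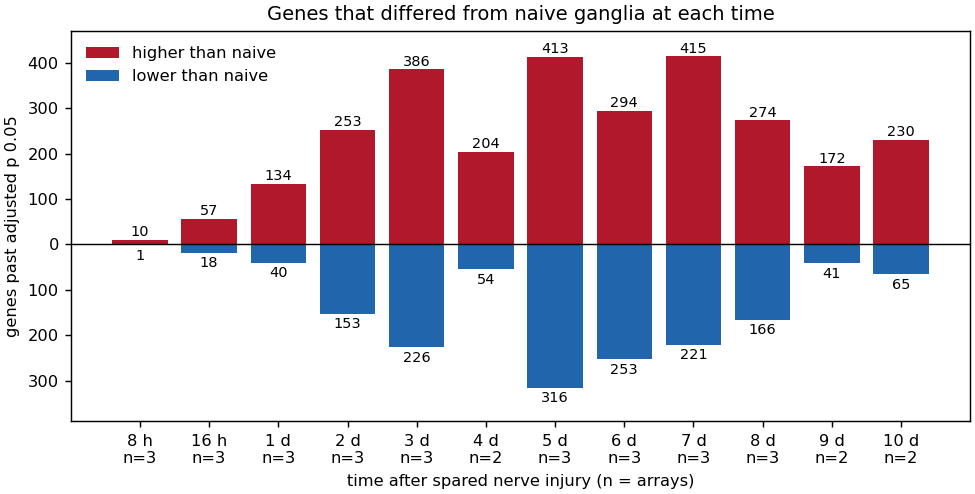
Genes past an adjusted p of 0.05 at each time, higher than naive above the line and lower below it, with the number of arrays per time. The counts were 11 genes at 8 h and 729 at 5 days, and they do not rank the times.

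The early phase (8 h, 16 h and 1 day; 9 arrays against 7 naive arrays) asks which transcripts change within the first day. Atf3 and Gadd45a had the largest rises. Atf3 rose by 2.93 ± 0.12 (7.62-fold, adjusted p = 4.86e-19). Gadd45a and Gadd45g, which encode stress response proteins, rose by 1.82 ± 0.13 and 1.09 ± 0.07. Flrt3, an adhesion molecule gene, rose by 1.42 ± 0.09, Gpr151 by 1.30 ± 0.11 and Kif22, a kinesin gene, by 1.19 ± 0.09. Timp1, an inhibitor of matrix metalloproteinases, rose by 1.23 ± 0.11, Socs3 by 1.22 ± 0.11 and Vgf, a neuropeptide precursor gene, by 0.91 ± 0.12. Steap1, a metalloreductase family gene, was below the detection level on all 7 naive arrays and at least 1.74-fold higher early, computed against that level with the normalization used here. Vstm2b fell by 0.62 ± 0.12 (adjusted p = 0.00195). Vwc2l, a secreted protein gene (-0.60 ± 0.09), Mrgprb5, a sensory receptor gene (-0.50 ± 0.11), Tmem108 (-0.50 ± 0.11) and Hs3st1, a heparan sulfate sulfotransferase gene (-0.42 ± 0.08), also fell. Falls were also called for Gbp2, an interferon-induced GTPase gene (-0.75 ± 0.19), and Cxcl10, an interferon-induced chemokine gene (-0.75 ± 0.17). Further falls were called for Scin, an actin-severing protein gene (-0.49 ± 0.13), Htr1d, a serotonin receptor gene (-0.42 ± 0.10), and Bahcc1 (-0.42 ± 0.11). These genes lay on their side of the naive mean on all 9 arrays, except Gpr151 (7 arrays) and Vstm2b (8 arrays), which the rule for naming them favours. In all, 118 genes passed, 89 higher and 29 lower. The count was 77 without naive replicate 1, 76 without 1-day replicate 3 and 65 with only the arrays of the groups compared. It was 212 with robust variances and array weights, 215 with a component of unchanged genes as a covariate and 232 with the skeletal muscle mean as a covariate. Calls ended without naive replicate 5 for Cxcl10 (adjusted p = 0.0518), without naive replicate 1 (adjusted p = 0.0526) or 2 (0.0626) or 1-day replicate 3 (0.0518) for Htr1d. They ended without any of 11 single arrays for Bahcc1 (adjusted p up to 0.147), 13 for Gbp2 (up to 0.119) and 17 for Scin (up to 0.143). With neqc background correction the calls of Cxcl10 (adjusted p = 0.0817), Gbp2 (0.0772) and Bahcc1 (0.0514) ended. With only the arrays of the groups compared those of Cxcl10 (adjusted p = 0.0528), Gbp2 (0.0525), Scin (0.0653) and Bahcc1 (0.0871) ended, and with the mean of its probes that of Gbp2 (0.134). The log2 differences of Gpr151 (0.73), Steap1 (0.35), Vwc2l (-0.39) and Tmem108 (-0.26) with neqc were over 1.5 times closer to 0.

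Of 24 measured nerve-injury and regeneration genes, 12 rose early and none fell, and 17 rose when adjusted over the list alone. The median log2 difference was 0.48 (camera adjusted p = 2.8e-44, and 2.28e-05 with an estimated correlation). Among genes named in advance, Gal rose by 0.45 ± 0.10 (adjusted p = 0.0143) and Csf1 by 0.46 ± 0.11 (adjusted p = 0.0351). Npy had a difference of 0.58 ± 0.18 (adjusted p = 0.131) and Sprr1a of 0.37 ± 0.16 (adjusted p = 0.374). The call of Gal ended without naive replicate 1 (adjusted p = 0.0525) or 3 (0.0519) and with only the arrays of the groups compared (0.0877). The call of Csf1 ended without any of 10 single arrays (adjusted p up to 0.0988), and over the settings that ended it the adjusted p ranged from 0.0514 without the filter to 0.222 with neqc. Of 13 immediate-early genes, 2 rose and none fell, 5 rose adjusted over the list alone (camera adjusted p = 3e-05, and 0.0185 with an estimated correlation). Junb rose by 0.54 ± 0.13, a call that ended without any of 10 single arrays (adjusted p up to 0.0932). Fos had a difference of 0.79 ± 0.22 (adjusted p = 0.0768). Of 11 repair Schwann cell genes, 2 rose, also adjusted over the list alone (camera adjusted p = 4.22e-05), namely Jun by 0.87 ± 0.12 and Bdnf by 0.66 ± 0.09. Of the 15 members of this list, 5 are also in another list, and RNA of whole ganglia does not give the cell type. The calls of this list, in any phase, therefore do not show a change in Schwann cells. Of 17 cholesterol synthesis genes, 2 rose and 5 rose adjusted over the list alone (camera adjusted p = 4.42e-06), among them Hsd17b7 by 0.28 ± 0.06. Of 13 unfolded protein response genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.00799, and 0.025 with an estimated correlation). Chac1 was at 0.47 ± 0.09.

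No member of the macrophage list (22 measured) or the extracellular matrix list (16 measured) passed, over all genes or adjusted over the list alone. Both camera calls (adjusted p = 0.00293 for each) were lost (adjusted p = 0.203 and 0.29 with an estimated correlation). Of 22 cytokine and chemokine genes, 2 rose and 1 fell, 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0359; adjusted p = 0.29 with an estimated correlation). Ccl12 rose by 0.76 ± 0.18, a call that ended without any of 6 single arrays (adjusted p up to 0.0639) and with neqc (0.0839). Of 13 glucocorticoid and systemic stress genes none passed, and 2 rose adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.259 with an estimated correlation). The cytokine call also ended without naive replicate 1 (adjusted p = 0.0981), 2 (0.0932) or 4 (0.0529), 8-hour replicate 2 (0.115), 16-hour replicate 1 (0.0569) or 1-day replicate 2 (0.0514) or 3 (0.073). The glucocorticoid call ended without naive replicate 3 (0.0534), 4 (0.11) or 7 (0.0707), 16-hour replicate 1 (0.0504) or 1-day replicate 2 (0.0722). No member of the sodium channel list (7 measured) or the potassium channel list (26 measured) passed, over all genes or adjusted over the list alone. Their camera adjusted p was 0.22 and 0.138. Scn10a (0.05 ± 0.10), Trpv1 (0.05 ± 0.15), Mrgprd (-0.02 ± 0.14), C1qa (0.04 ± 0.12) and Aif1 (0.01 ± 0.08) did not pass. Of 30 lists tested, 12 passed, all upward, and 5 held with an estimated correlation.

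The middle phase (2 to 5 days; 11 arrays against 7) asks what changes after the first day. Npy, Gpr151 and Atf3 had the largest rises. Npy rose by 4.29 ± 0.17 (19.5-fold, adjusted p = 1.44e-19), Gpr151 by 4.22 ± 0.11 (18.6-fold) and Atf3 by 3.78 ± 0.11 (13.7-fold). Sprr1a rose by 3.68 ± 0.16 (12.8-fold), Cckbr by 3.41 ± 0.16 (10.6-fold) and Gal by 2.81 ± 0.10 (7.02-fold). Tubb6, a tubulin gene, rose by 2.58 ± 0.19 and Wfdc3, a protease inhibitor family gene, by 2.46 ± 0.14. Speer3 and Speer1, of a rodent gene family best known from testis, were below the detection level on all 7 naive arrays and, with the normalization used here, at least 5.16-fold and 3.6-fold higher. Vstm2b fell by 1.26 ± 0.11 (adjusted p = 1.52e-10), Etv1, a transcription factor gene of large sensory neurons, by 0.82 ± 0.13. Htr3a, a serotonin-gated channel gene, fell by 0.80 ± 0.15, Thrsp, a lipogenesis gene, by 0.80 ± 0.16 and Cplx2, a synaptic release gene, by 0.79 ± 0.13. Hip1 (-0.72 ± 0.19), Tceal3 (-0.69 ± 0.13), Gng8, a G protein subunit gene (-0.69 ± 0.12), Chrna6, a nicotinic receptor subunit gene (-0.68 ± 0.11), and Sema7a, a semaphorin gene (-0.67 ± 0.09), also fell. Each of these 20 genes lay on its side of the naive mean on all 11 arrays, which the rule for naming them favours. In all, 1150 genes passed, 602 higher and 548 lower.

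In the middle phase, 21 of 24 nerve-injury and regeneration genes rose and none fell, and 22 rose adjusted over the list alone. The median log2 difference was 1.37 (camera adjusted p = 2.57e-55, and 4.6e-06 with an estimated correlation). Of 22 macrophage and microglia markers, 14 rose and none fell, 18 rose adjusted over the list alone. The median was 0.47 (camera adjusted p = 1.14e-14, and 0.00196 with an estimated correlation). Examples are the mannose receptor gene Mrc1 at 1.23 ± 0.13, Lgals3 at 0.97 ± 0.07 and Aif1 at 0.57 ± 0.08. Of 7 sodium channel genes, 4 fell and none rose, 5 fell adjusted over the list alone (camera adjusted p = 0.000113). Scn1a fell by 0.64 ± 0.11 and Scn4b by 0.49 ± 0.07. Scn10a, the channel of nociceptors, had a difference of -0.21 ± 0.09 (adjusted p = 0.162). Of 26 potassium channel genes, 8 fell and 1 rose, 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000471, and 0.0144 with an estimated correlation). Kcna2 fell by 0.61 ± 0.11 and Kcnk18 by 0.50 ± 0.10, and Kcnmb4 rose by 0.54 ± 0.11. Of 14 large-fibre neuron markers, 3 fell and none rose, 4 fell adjusted over the list alone (camera adjusted p = 0.0164, and 0.0281 with an estimated correlation). Among them were Etv1 and Nefm (-0.40 ± 0.11). Of 20 transduction channel genes, 5 fell and 6 fell adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.0634 with an estimated correlation). Htr3b fell by 0.67 ± 0.10 and Asic1 by 0.40 ± 0.07. The heat channel gene Trpv1 (-0.33 ± 0.15, adjusted p = 0.156) did not pass. Mrgprd, a marker of nonpeptidergic nociceptors, had a difference of -0.38 ± 0.13 (adjusted p = 0.0609).

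Of 7 complement genes, 3 rose, also adjusted over the list alone (camera adjusted p = 0.00313; adjusted p = 0.122 with an estimated correlation). C1qc rose by 1.10 ± 0.12, C1qb by 0.94 ± 0.12 and C1qa by 0.46 ± 0.12. Of 22 cytokine and chemokine genes, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00713; adjusted p = 0.187 with an estimated correlation). Csf1 rose by 1.37 ± 0.11 and Ccl8 by 1.29 ± 0.13. Of 16 extracellular matrix genes, 2 rose and 7 rose adjusted over the list alone (camera adjusted p = 0.00509; adjusted p = 0.306 with an estimated correlation). Lum rose by 0.55 ± 0.13 and Mmp2 by 0.50 ± 0.11. Of 11 repair Schwann cell genes, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00985, and 0.0228 with an estimated correlation). Gap43, a growth cone protein gene, rose by 1.12 ± 0.21 and Jun by 0.79 ± 0.12. Of 17 proliferation genes, 3 rose and 5 rose adjusted over the list alone (camera adjusted p = 0.000475, and 0.0498 with an estimated correlation). Prc1 was at 1.43 ± 0.09. Of 13 unfolded protein response genes 2 rose and 4 rose adjusted over the list alone (camera adjusted p = 0.00082), with Chac1 at 1.27 ± 0.09 and Atf4 at 0.27 ± 0.05. Of 30 lists tested, 12 passed, 8 upward and 4 downward, and 8 held with an estimated correlation. The middle count was 2127 with robust variances and array weights. With neqc the log2 differences of Speer3 (1.37), Wfdc3 (1.37), Speer1 (0.96), Csf1 (0.67), Ccl8 (0.45), Aif1 (0.24), C1qa (0.21), Hip1 (-0.45), Thrsp (-0.35) and Kcnk18 (-0.25) moved over 1.5 times closer to 0, and all kept their calls.

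The late phase (6 to 10 days; 13 arrays against 7) covers the end of the series. Npy rose by 5.40 ± 0.17 (42.1-fold, adjusted p = 9.78e-23), and Gpr151 by 4.14 ± 0.10 and Sprr1a by 4.14 ± 0.15 (17.6-fold each). Cckbr rose by 3.86 ± 0.16 (14.5-fold), Atf3 by 3.57 ± 0.11 (11.9-fold) and Gal by 2.77 ± 0.09 (6.8-fold). Ecel1 rose by 2.85 ± 0.13, Car3 by 2.56 ± 0.26 and Tubb6 by 2.42 ± 0.18, and Speer3 was at least 3.42-fold higher. Calb2 fell by 1.30 ± 0.10 (adjusted p = 1.76e-12), with a difference of -0.81 on its other probe, and Vstm2b by 1.30 ± 0.11. The serotonin-gated channel genes Htr3a (-0.97 ± 0.15) and Htr3b (-0.74 ± 0.10), and Hapln4, a perineuronal matrix gene (-0.81 ± 0.13), fell. Whrn (-0.79 ± 0.08), Gng8 (-0.79 ± 0.11), Lgi3, a secreted neuronal protein gene (-0.76 ± 0.08), Omg, a myelin glycoprotein gene (-0.73 ± 0.09), and Tafa2, a secreted neuronal protein gene (-0.72 ± 0.09), also fell. Each of these 20 genes lay on its side of the naive mean on all 13 arrays, which the rule for naming them favours. In all, 1144 genes passed, 606 higher and 538 lower.

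In the late phase, 20 of 24 nerve-injury and regeneration genes rose and none fell, and 23 rose adjusted over the list alone. The median log2 difference was 1.09 (camera adjusted p = 1.63e-58, and 4.6e-06 with an estimated correlation). The macrophage, complement and cytokine lists passed upward. Of 22 macrophage and microglia markers, 17 rose and none fell, 18 rose adjusted over the list alone. The median was 0.67 (camera adjusted p = 1.52e-26, and 6.72e-05 with an estimated correlation). Examples are Mrc1 at 1.14 ± 0.13, Fcer1g at 1.05 ± 0.10, Lgals3 at 0.98 ± 0.07 and Aif1 at 0.68 ± 0.08. Of 7 complement genes, 4 rose and 6 rose adjusted over the list alone (camera adjusted p = 3.91e-08, and 0.00582 with an estimated correlation). C1qc rose by 1.33 ± 0.12, C1qb by 1.29 ± 0.12 and C1qa by 0.79 ± 0.12. Of 22 cytokine and chemokine genes 10 rose and 11 rose adjusted over the list alone (camera adjusted p = 9.02e-09, and 0.00582 with an estimated correlation). Examples are Ccl8 at 1.33 ± 0.13, Csf1 at 1.24 ± 0.11 and Ccl12 at 1.06 ± 0.16. Of 16 extracellular matrix genes, 9 rose and 10 rose adjusted over the list alone. The median was 0.42 (camera adjusted p = 6.61e-10, and 0.0274 with an estimated correlation). Col1a1 rose by 0.80 ± 0.14, Lum by 0.64 ± 0.12 and Mmp2 by 0.62 ± 0.11. Of 16 antigen presentation genes, 4 rose and 5 rose adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.187 with an estimated correlation). Cd74 rose by 0.71 ± 0.10 and H2-Ab1 by 0.67 ± 0.11. Of 11 repair Schwann cell genes, 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00985, and 0.0228 with an estimated correlation). Gap43 was at 0.93 ± 0.20, Jun at 0.69 ± 0.11 and Shh at -0.55 ± 0.12. Of 13 unfolded protein response genes 2 rose and 3 rose adjusted over the list alone (camera adjusted p = 0.0011), with Chac1 at 1.16 ± 0.09. The camera calls of 15 myelin genes (2 rose, 3 adjusted over the list alone; adjusted p = 0.00189), 17 proliferation genes (2 rose, 2 adjusted over the list alone; adjusted p = 0.00522) and 17 cholesterol synthesis genes (2 rose, 2 adjusted over the list alone; adjusted p = 0.0342) were lost (adjusted p = 0.284, 0.121 and 0.0524 with an estimated correlation). The cholesterol synthesis call also ended without naive replicate 7 (adjusted p = 0.0515) or 6-day replicate 1 (0.0559).

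The lists of sodium channel genes, potassium channel genes and large-fibre neuron markers passed downward in the late phase. Of 7 sodium channel genes, 4 fell and none rose, 5 fell adjusted over the list alone (camera adjusted p = 0.000156), with Scn1a at -0.59 ± 0.10 and Scn4b at -0.46 ± 0.07. Of 26 potassium channel genes, 10 fell and 1 rose, 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.06e-06), with Kcnk1 at -0.54 ± 0.07 and Kcnk18 at -0.55 ± 0.10. Kcna1, with a difference of -0.56 ± 0.22 (adjusted p = 0.105), did not pass. Of 14 large-fibre neuron markers, 4 fell and 5 fell adjusted over the list alone (camera adjusted p = 0.000156). The 4 are Etv1 (-0.67 ± 0.12), the proprioceptor marker Pvalb (-0.59 ± 0.16), Faim2 (-0.59 ± 0.11) and Cntnap2 (-0.44 ± 0.11). The log2 signal of Pvalb was highest on 8-day replicate 1 (13.85), the array with the highest skeletal muscle mean (11.88). The transduction channel list (3 of 20 fell, 4 adjusted over the list alone; camera adjusted p = 0.00893) and the nonpeptidergic nociceptor list (3 of 16 fell, 3 adjusted over the list alone; camera adjusted p = 0.034) lost their calls (adjusted p = 0.105 and 0.29 with an estimated correlation). The nociceptor genes Scn10a (-0.12 ± 0.09, adjusted p = 0.535), Trpv1 (-0.15 ± 0.14, adjusted p = 0.616) and Mrgprd (-0.20 ± 0.13, adjusted p = 0.419) did not pass. The cold channel gene Trpm8 was above the detection level on 2 of 7 naive arrays and on 0 of 9 early, 1 of 11 middle and 0 of 13 late arrays, so these arrays cannot show whether it changed. Of 30 lists tested, 18 passed, 13 upward and 5 downward, and 10 held with an estimated correlation. The late count was 1728 with a component of unchanged genes as a covariate. The nonpeptidergic nociceptor call also ended without naive replicate 4 (adjusted p = 0.0529), 6-day replicate 3 (0.0502), 8-day replicate 1 (0.056), 9-day replicate 1 (0.105) or 10-day replicate 1 (0.0717). The late log2 difference of Faim2 was -0.39 with the mean of its probes. With neqc those of Ecel1 (1.55), Car3 (1.59), Speer3 (0.92), Csf1 (0.59), Ccl12 (0.52), Ccl8 (0.46), C1qa (0.39), Aif1 (0.29), Calb2 (-0.83), Tafa2 (-0.46) and Kcnk18 (-0.27) moved over 1.5 times closer to 0 and kept their calls.

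**Figure D3:**
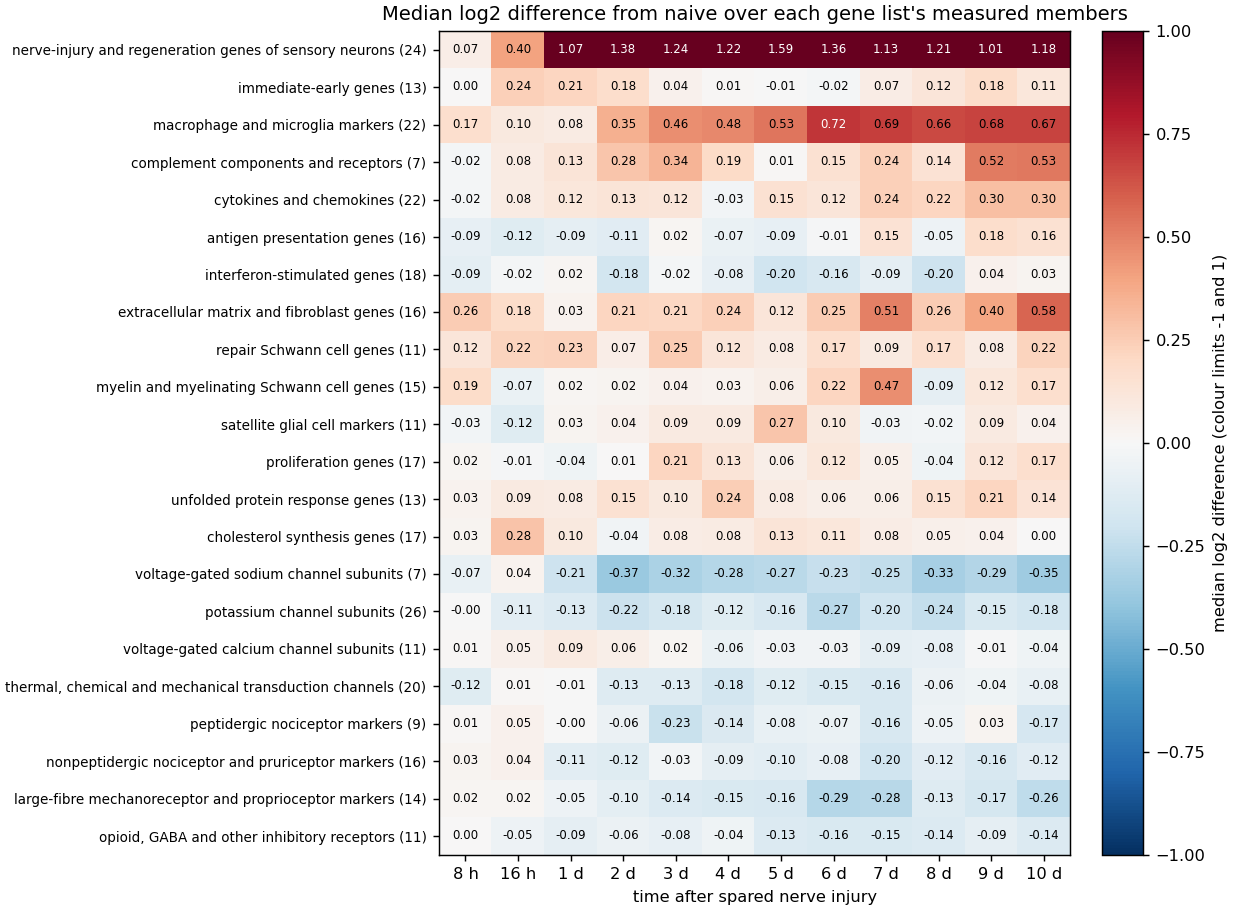
Median log2 difference from naive over the measured members of 22 fixed gene lists (number of members in parentheses) at each time, with red above and blue below naive. The median of the injury list was 0.07 at 8 h and 1.59 at 5 days, and that of the macrophage list 0.17 at 8 h and 0.72 at 6 days.

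The late phase minus the early phase (13 arrays against 9) tests the change over time itself, and the naive arrays cancel in it. Npy was higher late by 4.82 ± 0.16 (28.2-fold, adjusted p = 9.21e-22), Sprr1a by 3.77 ± 0.14 and Cckbr by 3.38 ± 0.14. Gpr151 was higher by 2.83 ± 0.10, Ecel1 by 2.71 ± 0.12 and Gal by 2.31 ± 0.09. Nts, which encodes neurotensin, was higher by 2.25 ± 0.21, with 0.48 on its other probe, Car3 by 1.96 ± 0.24 and Speer3 by 1.87 ± 0.11. Lipn, a lipase gene, was below the detection level on all 9 early arrays and at least 2.98-fold higher late. Calb2 was lower late by 1.31 ± 0.09 (adjusted p = 2.58e-13). Also lower were Socs3 (-0.91 ± 0.10), Htr3a (-0.73 ± 0.13), Steap1 (-0.73 ± 0.09), Pvalb (-0.69 ± 0.15) and Vstm2b (-0.68 ± 0.10). So were Slc10a6, a transporter gene (-0.66 ± 0.07), Olfr920, an olfactory receptor gene (-0.62 ± 0.09), Thrsp (-0.62 ± 0.14) and Tafa2 (-0.60 ± 0.08). All 13 late arrays lay on the same side of the early mean for these genes, which the rule for naming them favours. The exception was 8-day replicate 1 for Pvalb. Atf3 was higher late by 0.64 ± 0.10 and Csf1 by 0.78 ± 0.10. Scn10a (-0.17 ± 0.08), Trpv1 (-0.21 ± 0.13) and Mrgprd (-0.17 ± 0.12) did not pass. In all, 745 genes passed, 463 higher and 282 lower.

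Of 24 nerve-injury and regeneration genes, 13 were higher and 2 lower late than early, also adjusted over the list alone. The camera adjusted p was 7.61e-22, and 0.00148 with an estimated correlation. Macrophage markers were higher for 16 of 22, and for 18 adjusted over the list alone. The median was 0.57 (camera adjusted p = 3.46e-27, and 6.72e-05 with an estimated correlation). Examples are Fcer1g at 0.88 ± 0.09, Lgals3 at 0.85 ± 0.07 and Aif1 at 0.66 ± 0.07. Complement genes were higher for 4 of 7, also adjusted over the list alone (camera adjusted p = 1.72e-08, and 0.00557 with an estimated correlation). C1qb was higher by 1.18 ± 0.11 and C1qa by 0.75 ± 0.11. Cytokine and chemokine genes were higher for 9 of 22, with 9 higher and 1 lower adjusted over the list alone. Their camera adjusted p was 1.2e-07, and 0.00913 with an estimated correlation. Antigen presentation genes were higher for 5 of 16, and for 7 adjusted over the list alone (camera adjusted p = 4.21e-05, and 0.0205 with an estimated correlation). Cd74 was at 0.95 ± 0.09, H2-Ab1 at 0.94 ± 0.11 and H2-Eb1 at 0.85 ± 0.09. Extracellular matrix genes were higher for 5 of 16, and for 9 adjusted over the list alone (camera adjusted p = 2.06e-06; adjusted p = 0.0975 with an estimated correlation), with Lum at 0.64 ± 0.11. Proliferation genes were higher for 2 of 17 and for 3 adjusted over the list alone (camera adjusted p = 0.00616; adjusted p = 0.124 with an estimated correlation), with Prc1 at 1.34 ± 0.08. Myelin genes were higher for 2 of 15, also adjusted over the list alone (camera adjusted p = 0.00649; adjusted p = 0.31 with an estimated correlation).

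Lower late than early were 2 of 7 sodium channel genes and 3 adjusted over the list alone (camera adjusted p = 0.000471, and 0.0137 with an estimated correlation). Scn1a was at -0.51 ± 0.10 and Scn4b at -0.37 ± 0.07. Among 26 potassium channel genes 7 were lower, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.21e-05), such as Kcnk1 at -0.39 ± 0.07. Among 14 large-fibre neuron markers 4 were lower, and 10 adjusted over the list alone (median -0.26, camera adjusted p = 2.31e-06), such as Pvalb and Faim2 (-0.52 ± 0.10). Among 9 peptidergic nociceptor markers 2 were lower and 1 higher, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.0632 with an estimated correlation). Bdnf was lower by 0.57 ± 0.08. Among 20 transduction channel genes 3 were lower, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.113 with an estimated correlation). Among 23 oxidative phosphorylation genes 1 was lower, also adjusted over the list alone (camera adjusted p = 0.0179, and 0.0261 with an estimated correlation). The call of this list ended without 16-hour replicate 3 (adjusted p = 0.055). Of 30 lists tested, 16 passed, 8 upward and 8 downward, and 10 held with an estimated correlation. The count of genes was 1134 with a component of unchanged genes as a covariate. The log2 difference of Nts was 1.37 with the mean of its probes. With neqc those of Ecel1 (1.52), Car3 (1.30), Speer3 (0.83), Lipn (0.79), Csf1 (0.40), C1qa (0.37), Aif1 (0.29), Calb2 (-0.84), Tafa2 (-0.37), Thrsp (-0.28), Steap1 (-0.26) and Olfr920 (-0.21) moved over 1.5 times closer to 0 and kept their calls.

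Muscle markers differed between single arrays. No skeletal muscle gene passed in any phase, over all genes or adjusted over the list alone. The list of 13 had a median log2 difference of 0.83 early (camera adjusted p = 0.000563; adjusted p = 0.378 with an estimated correlation). It was 0.85 late (camera adjusted p = 0.0239; adjusted p = 0.589 with an estimated correlation). Its mean log2 signal was 11.88 on 8-day replicate 1, 10.03 on the next highest array and 7.17 at the median. The late call ended without naive replicate 3 (adjusted p = 0.0549), 4 (0.0529) or 5 (0.0527), 8-day replicate 1 (0.134), 9-day replicate 1 (0.123) or 10-day replicate 1 (0.0553). The fast myosin gene Myl1 had a difference of 1.32 ± 0.87 late (adjusted p = 0.424) and the calcium pump gene Atp2a1 of 1.22 ± 0.74 (adjusted p = 0.364). Neutrophil and mast cell markers had a median of 0.48 early (none of 16 passed, 2 rose adjusted over the list alone; camera adjusted p = 8.06e-06; adjusted p = 0.142 with an estimated correlation). Late it was 0.24 (none passed, over all genes or the list alone; camera adjusted p = 0.00293; adjusted p = 0.31 with an estimated correlation). At 8 h the median was 0.92, with no member past the threshold, and the mean signal of the list lay between 8.67 and 9.17 on the 3 arrays at 8 h and between 7.72 and 8.33 on the 7 naive arrays, values chosen after they were seen. S100a9 had a difference of 0.71 ± 0.34 early (adjusted p = 0.415). Of 7 clock output genes, 2 passed at 16 h, where Dbp fell by 1.87 ± 0.24 (adjusted p = 4.46e-06) and Nr1d1 by 0.56 ± 0.13 (adjusted p = 0.0194). At 8 days 3 passed, and Dbp fell by 1.27, Ciart by 0.64 and Nr1d1 by 0.60. These genes were chosen after their values were seen.

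**Figure D4:**
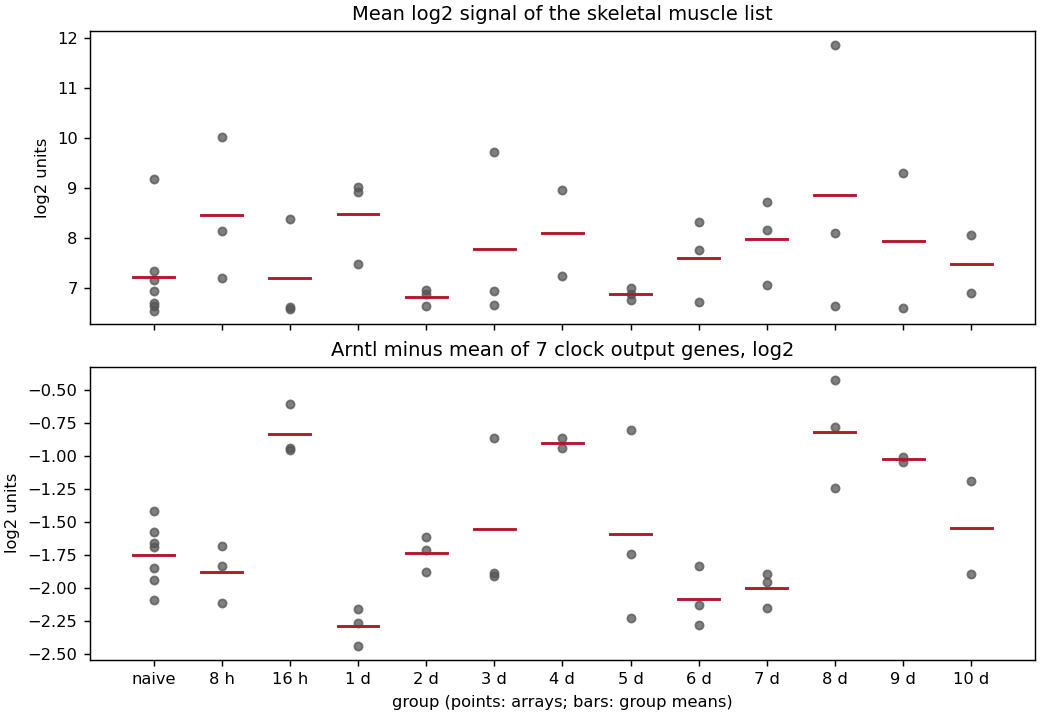
Mean log2 signal of the skeletal muscle list (upper panel) and Arntl minus the mean of 7 clock output genes (lower panel) on each array (points), with group means (bars). 8-day replicate 1 has the highest muscle mean, 11.88, and the clock score at 16 h is -0.83 on average.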

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

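The tests of the 3 patterns weighed below were all chosen after the result was seen. Among the 7 naive arrays, 1 array lay far from the others by its gap to the nearest array over the whole range for 7 of 107 genes tested, and chance gives about 1 in 20. Naive replicate 2 was the highest for Gng8 (0.808) and Timp1 (0.616). Naive replicate 4 was the lowest for C1qb (0.758) and Htr3b (0.638) and the highest for S100a9 (0.661), and naive replicate 6 the highest for the muscle gene Atp2a1 (0.649). Naive replicate 3 was the lowest for the clock gene Ciart (0.610). No cause was tested.

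Expression differed between the late and early phases, by a test of the difference itself, for 745 genes. The series holds no arrays of sham surgery, so the injury and the surgery were not told apart for them. Higher late, in log2, were Npy (4.82), Sprr1a (3.77), Cckbr (3.38), Gpr151 (2.83), Ecel1 (2.71), Gal (2.31), Nts (2.25), Car3 (1.96), Speer3 (1.87), Prc1 (1.34), C1qb (1.18), Cd74 (0.95), H2-Ab1 (0.94), Fcer1g (0.88), Lgals3 (0.85), H2-Eb1 (0.85), Csf1 (0.78), C1qa (0.75), Aif1 (0.66), Lum (0.64) and Atf3 (0.64). Lipn, below the detection level on all 9 early arrays, was higher by at least 1.57 with the normalization used here. Lower late were Calb2 (-1.31), Socs3 (-0.91), Htr3a (-0.73), Steap1 (-0.73), Pvalb (-0.69), Vstm2b (-0.68), Slc10a6 (-0.66), Olfr920 (-0.62), Thrsp (-0.62), Tafa2 (-0.60), Bdnf (-0.57), Faim2 (-0.52), Scn1a (-0.51), Aldoc (-0.48), Aqp4 (-0.43), Kcnk1 (-0.39) and Scn4b (-0.37). Of 926 kept probes with no gene in the probe table, 84 passed in the late phase, a signal in probes that the comparisons of genes do not use.

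Car3, which muscle and fat express, rose in the middle and late phases. With the skeletal muscle mean as a covariate its late log2 difference was 2.31 ± 0.20 (adjusted p = 9.93e-11, n = 13 against 7). This argues against muscle tissue in some samples as the source of the late rise. It does not argue against muscle tissue being present, since muscle markers differed between single arrays. The fat gene Adipoq reached at most 0.62 late (its log2 difference plus 2 standard errors), below the 2.04 of Car3 minus 2 standard errors. This 1 gene argues against fat tissue as the source of the rise. Only 3 adipocyte genes were measured, so fat tissue is not ruled out. The injury, the surgery, other tissue and other cells were not told apart, since the series holds naive arrays and no arrays of sham surgery.

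Of 7 clock output genes, Dbp and Nr1d1 differed between 16 h and naive arrays, and the labels give no time of collection. If the tissue at 16 h was taken at another time of day than at whole days, the clock score (Arntl minus the mean of 7 clock output genes) would differ, and it was -0.83 ± 0.19 (SD, 3 arrays) against -1.59 ± 0.58 (27 arrays; exact permutation p = 0.0271). However, 6 arrays at whole days lay above the lowest score at 16 h, and the mean was -0.81 at 8 days, -0.90 at 4 days and -1.02 at 9 days, so the explanation stays open; this condition on the whole-day arrays was added after the permutation p had been seen. With the first component of genes with no difference over time as a covariate, Dbp at 16 h had a log2 difference of -1.87 ± 0.23 (adjusted p = 1.04e-06). Those genes were chosen for no difference between groups, so the component could hardly move this value. Variation between arrays within groups therefore stays open. An effect of the injury at 16 h is not excluded.

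10-day replicate 2, whose detection column is named for 216 h, could be a 9-day sample labelled as 10 days. Over the clock genes its distance was 0.558 to the mean of the 9-day arrays and 1.47 to 10-day replicate 1. Only 7 of 31 other injured arrays were nearest to the rest of their own group (22.6%), so this distance cannot tell. No biological explanation was tested.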

How the results depend on the processing

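The alternatives were fixed before the data were examined, except the covariates and the move of 10-day replicate 2, which were chosen after a result was seen. The neqc processing was itself the plan, and the processing used in its place was chosen after an initial neqc fit. Limits: the number of arrays limits precision, groups hold 2 or 3 arrays beside 7 naive arrays, and the deposited detection columns follow their own array's signal on 3 of 40 arrays. No value past the threshold in the processing used here or in the alternative reversed its direction. Changes of sign in other values were not counted. Of 591 gene values, 275 were past the threshold. A value kept its status if it stayed past or stayed not past. Of the 591, 588 kept their status with the authors' deposited log2 values and without background correction. The number was 577 without the filter, 580 with the mean of a gene's probes and 581 with blocks by sample-number range. With blocks by replicate number 531 kept their status and 54 of the 275 calls ended. With only the arrays of the groups compared 561 kept their status and 21 of the 275 calls ended. The number that kept their status was 548 with robust eBayes and array weights, 554 with the component of unchanged genes and 573 with the muscle mean. It was 576 with the move of 10-day replicate 2. With the stricter filter 566 of 568 kept their status, and with neqc 570 of 583. With 1 array left out, 23193 of 23640 gene values and 4711 of 4800 list results kept their status. Of the 275 calls of genes, 40 ended without at least 1 of the single arrays.

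Robust eBayes with array weights gave 47 genes at 8 h, 410 at 16 h, 489 at 1 day, 995 at 2 days, 3315 at 3 days, 575 at 4 days, 1377 at 6 days, 212 early, 2127 in the middle phase and 4553 at any time (cause not tested). Blocks by replicate number gave 4 at 8 h, 33 at 16 h, 92 at 1 day, 396 at 3 days, 460 at 5 days, 379 at 7 days, 258 at 8 days, 141 at 9 days, 181 at 10 days, 39 early, 649 in the middle phase, 551 late and 505 at any time. Numbers 4 to 7 occur only among naive arrays, so fewer naive arrays carry that contrast, and replicate numbers do not pair arrays (mean correlation 0.008 for the same number and -0.003 for other numbers). With only the arrays of the groups compared, fewer arrays estimate the spread, and the counts were 20 at 8 h, 31 at 16 h, 363 at 3 days, 139 at 9 days and 65 early. The first component of genes with no difference over time as a covariate gave 26 at 8 h, 238 at 16 h, 266 at 1 day, 631 at 2 days, 1150 at 3 days, 507 at 4 days, 1061 at 7 days, 721 at 8 days, 369 at 9 days, 461 at 10 days, 215 early, 1728 late, 1134 for late minus early and 1472 at any time (cause not tested). The skeletal muscle mean as a covariate gave 315 at 1 day, 767 at 8 days and 232 early. With 10-day replicate 2 counted among the 9-day arrays there were 20 genes at 8 h and 332 at 9 days (cause not tested). Camera with an estimated correlation left 5 lists early, 10 late and 10 for late minus early, and fry 5 early. Over the 120 list results, fry ended 10 calls and added 9. Blocks by slide were not run, since the files give no slides.

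With 1 array left out, the counts ranged from 3 to 20 at 8 h, 37 to 98 at 16 h, 83 to 248 at 1 day, 193 to 443 at 2 days, 323 to 1040 at 3 days, 85 to 290 at 4 days, 407 to 824 at 5 days, 299 to 604 at 6 days, 305 to 687 at 7 days, 264 to 511 at 8 days, 70 to 234 at 9 days and 87 to 314 at 10 days. They ranged from 76 to 162 early, 864 to 1253 in the middle phase, 935 to 1225 late, 602 to 783 for late minus early and 688 to 1114 at any time. The highest count came without 3-day replicate 1 at 16 h, 2, 3, 7, 8, 9 and 10 days. This also held late, for late minus early and at any time (cause not tested). Lists past the threshold ranged from 9 to 13 early, 12 to 12 in the middle phase, 16 to 18 late and 15 to 19 for late minus early.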

Other observations

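No test in this part was chosen after its result was seen, but the processing used in place of neqc was chosen after an initial neqc fit. Several other lists did not pass with camera. Of 18 interferon-stimulated genes, 1 fell early and in the middle phase, namely Gbp2 (-0.67 ± 0.18 in the middle phase, adjusted p = 0.0145; 0.0557 without naive replicate 5). Late 1 rose, namely Ifitm3 (0.28 ± 0.08, adjusted p = 0.0169, n = 13 against 7), a call that ended without 9-day replicate 1 (adjusted p = 0.0529). The camera adjusted p of this list was 0.828 early, 0.307 in the middle phase, 0.484 late and 0.577 for late minus early. Of 11 voltage-gated calcium channel genes, 1 rose and 1 fell in the middle phase and 1 rose and 2 fell late, with Cacna2d1, the gabapentin target gene, at 0.71 ± 0.12 late (list adjusted p = 0.545, 0.868, 0.606 and 0.209). Of 11 inhibitory receptor genes, 3 rose and 2 fell in the middle phase and 1 rose and 2 fell late, and Npy1r, a receptor gene for neuropeptide Y, rose by 0.51 ± 0.09 early (list adjusted p = 0.821, 0.611, 0.385 and 0.306). Of 11 satellite glia markers, none passed early, 2 rose in the middle phase and 1 late (list adjusted p = 0.821, 0.223, 0.268 and 0.103). With fry this list passed upward in the middle phase (adjusted p = 0.0054), late (0.0138) and for late minus early (0.000471), and the inhibitory receptor list downward late (0.0396). Gfap, a glial filament gene named in advance, was not above the detection level on at least 3 arrays. None of 11 endothelial markers passed in a comparison of phases (list adjusted p = 0.921, 0.699, 0.901 and 0.818), and of 13 clock genes 1 rose in each phase, namely Nfil3 (1.08 ± 0.11 late; list adjusted p = 0.103, 0.664, 0.733 and 0.482).

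Other cells and tissue: none of 5 erythrocyte genes passed early (median log2 difference 0.32, camera adjusted p = 0.0389; adjusted p = 0.269 with an estimated correlation), a call that ended without any of 6 single arrays, with the highest adjusted p, 0.148, without naive replicate 5. For late minus early, 1 of 5 erythrocyte genes was lower (camera adjusted p = 0.0423; adjusted p = 0.277 with an estimated correlation), with the highest adjusted p, 0.132, without 1-day replicate 3. Of 5 central oligodendrocyte and spinal cord markers, 2 were lower late than early (camera adjusted p = 0.0103, and 0.0271 with an estimated correlation). They were Aldoc (-0.48 ± 0.08) and Aqp4 (-0.43 ± 0.10, and -0.21 with neqc). Only 4 lymphocyte and 3 adipocyte genes were measured, so these lists were not tested. In 11 of 120 list tests the median, the mean and the camera direction differed in sign, and 0 of these passed.

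Whether chance could give as many genes or lists was tested with 100 splits of the arrays into groups of the same sizes, counting the labelled split, and these tests were written before the results were seen. The number of splits with at least the labelled count was 1 of 100 for genes at any time (791, highest other 23), 8 h (11 and 1), 16 h (75 and 5), 2 days (406 and 1), 5 days (729 and 21), 6 days (547 and 2), 7 days (636 and 5) and 8 days (440 and 5). It was also 1 of 100 for the early phase (118 and 41), the middle phase (1150 and 780), the late phase (1144 and 154) and late minus early (745 and 80). It was 2 of 100 at 1 day (174 and 181, the latter with naive replicate 4 grouped with 1-day replicates 2 and 3) and 3 of 100 at 3 days (612 and 1025, the latter with naive replicate 2 grouped with 3-day replicates 2 and 3). For lists it was 1 of 100 in the middle phase (12 and 11), 2 late (18 and 18) and 3 for late minus early (16 and 18). In all of these chance can be excluded at 1 in 20 for each count taken singly, not for each gene or list. The tests were not adjusted for the number of counts. For the early lists 7 of 100 splits had at least as many (12, highest other 13), so chance cannot be excluded for their number. The median of the other splits was 6 lists early, 5 in the middle phase, 7 late and 7 for late minus early. For each gene count it was 0. Camera at the preset correlation thus often passed lists under other splits, so a single list call is weak evidence without the estimated correlation.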
